A study of Mus musculus with 3072 samples.

How the data were processed

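The deposited data come from a screen by SPAR-seq, in which a multiplexed RT-PCR amplifies chosen exon regions of many genes from each well and barcoded sequencing reads them out. Amplicons of 108 genes were measured in N2A cells, a mouse neuroblastoma line, after 1536 treatments in 2 replicates each, which gave 3072 libraries on 16 plates per replicate. Per the labels' protocols, pools of siRNA were transfected at 50 nM and RNA was taken 48 hours later. The labels name the gene that was knocked down in 2832 libraries, of 1416 genes with 2 libraries each. The other libraries are 64 with a non-targeting siRNA, 64 mock transfections, 64 with siRNA against Mbnl1 and Mbnl2 together (Mbnl1+2) and 48 untreated. The group in the labels matched the authors' deposited treatment table in all 3072 libraries, with 0 differences. Sample titles name no plate. Plates were taken as consecutive runs of treatments, numbered alike in both replicates. On that numbering they had 0 differences from the treatment table, which is not a check of plate labels. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

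The authors deposited whole read counts per event and library, in which every element of a gene carries the count of its amplicon. A second deposited table gives the percent spliced in (PSI), from 0 to 100 percent, per exon element and library, without further normalization. Deposited PSI changes per treatment, in percentage points, had been normalized by the authors against a reference not given in the sources used here. The deposited strictly standardized mean difference (SSMD) is a score per treatment from the same step. The authors' expression table holds log2 fold changes of amplicon reads, their log2 counts per 1000000 reads, and adjusted p-values. The submitters' processing notes name CASAVA 1.8, Bowtie, TopHat and edgeR, and the builds NCBIM37, mm9 and mm10, with no role for any of them. Coordinates are printed as the authors' deposited design table gives them, 1-based. That table states no build, and only 17 of its 107 genes found in a GRCm38 gene table had the first exon inside the gene of that name there, although 107 of 107 were on the same chromosome. All per-sample columns of the tables used had a sample, leaving 0 unused.

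Library totals over the 108 amplicons had a median of 32459.5 reads. Lowest and highest totals were 6 and 105587 reads in knockdowns, 8686 and 73728 in non-targeting, 13015 and 74193 in mock, 1252 and 52078 in untreated and 9761 and 64515 in Mbnl1+2 libraries. Totals were under 1000 reads in 5 libraries and under 10000 in 13. The Mef2d amplicon alone took 30.2% of all reads and the 10 largest amplicons 72.4%, while the median count for Gapdh was 0. PSI values resting on fewer than 20 reads were left out for that event and library. Of 104 elements that the deposited event table marks as main alternative events, 65 in 64 genes had at least 20 reads in at least 50% of libraries and were tested. Tested events had a median of 106 reads per library, with quartiles of 44 and 359. At a PSI near the middle of the scale, the 95% Wilson interval spans 20.1 points on either side with 20 reads and 9.35 points with 106. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Counts were compared between the libraries of each treatment, to look for a library deposited more than once. There were 0 identical pairs, and over the 1531 treatments with at least 1000 reads in both libraries the lowest chi-square per degree of freedom was 1.62 and the median 9.03.

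PSI was fitted per event by least squares with the group and the plate as terms, over all libraries. The plate term had 16 levels, each shared by both replicates, so the main fit did not model the replicate or its batch. An alternative called the replicate block gave each plate of each replicate a level of its own. The variance was moderated across events with limma 3.58.1 (squeezeVar) and p-values were two-sided and adjusted by the Benjamini-Hochberg method. For mock, untreated and Mbnl1+2 libraries the adjustment ran over the events, and a call needed an adjusted p under 0.05 and a difference of at least 5 points from non-targeting. For the gene knockdowns the adjustment ran over all pairs of event and knockdown, and a call needed an adjusted p under 0.05, a change of at least 10 points and both libraries on the same side of the non-targeting mean. The same test was run on each control well as if it were a knockdown, which measures the background. Errors after ± are standard errors (SE) from this fit unless SD is written. The variance of an event is pooled over all groups, so an SE does not measure the spread between the 2 libraries of a given knockdown. In knockdowns n = 2 libraries against up to 64 non-targeting libraries.

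Amplicon counts were tested with edgeR 4.0.16 (TMM normalization, glmQLFit and glmQLFTest) on 278 libraries, with plate and group as terms and no filter on low counts. Those libraries were all control groups and the knockdowns of the 19 genes that have an amplicon of their own. Standard errors of log2 changes are Wald errors of that fit. Where a gene had 0 reads, a bound was taken from 3 reads over both libraries. Mean numbers of called events in 26 gene lists were compared with all other knockdowns by two-sided permutation tests of 100000 resamples. Microexons of 3 to 27 nt were compared with longer cassette exons in the same way, over events, which are not independent replicates. Profiles of PSI change within complexes were compared with 10000 random sets of knockdowns that had at least 1 call. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

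Each procedure was tested on simulated data. In the screen, 29.9% of simulated changes of 10 points were called, 71.6% at 15 points, 77.7% at 20 and 88.8% at 30, and 9 of 89477 unchanged pairs were called, with 65 events per step. Simulated noise was equal for all libraries of an event, whatever their reads, with no shift between replicates, and few pairs were changed. These rates therefore need not hold for the real screen, whose background was measured in the control wells. For Mbnl1+2, 10 of 10 simulated changes of 5 points and 10 of 10 of 10 points passed the adjusted p threshold, and 0 of 45 unchanged events were called. The changed events were counted without the minimum difference that a call needed in that comparison, so these counts are not rates of calls. In simulated counts of 108 amplicons for that comparison, edgeR called all 12 at a log2 change of 0.5, all 12 at 1 and all 6 at 2, with 4 of 78 unchanged amplicons. Of 19 simulated own-gene falls, 18 were called.

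Groups, tests, thresholds, gene lists and the alternatives were fixed before the data were examined, apart from 3 alternatives added later. These used only the non-targeting wells in position A01, only those in D09, or left out knockdown libraries under 10000 reads. The fixed alternatives changed the read minimum to 5 or 100, the PSI scale to a logit bounded at 1 and 99, the plate term, the controls, the minimum change to 5 or 20 points, the weights, the replicates and the count normalization, with DESeq2 1.42.0 as another count tool. Genes were named by a rule. For Mbnl1+2 the rule took the 10 largest increases and 10 largest decreases among called events. For the screen it took the 25 knockdowns with most called events, ties ranked by summed absolute change, with the largest called event of each, and the 10 events called most and 5 called least often. It took the 4 members with most calls of each list with an adjusted p under 0.05 and the top member of any other list, 30 regulators with up to 3 events each, and the 10 largest own-gene falls with any that rose. Since 9 events shared the lowest count, all 9 are named.

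Replicate numbers pair the libraries. The authors' deposited treatment table puts replicate 1 and replicate 2 in different batches (L1 and L2 against L3 and L4), and the differences between the replicates correlated between groups at r from 0.418 to 0.747 across events. Batches L1 and L3 hold plates 1 to 8, and L2 and L4 plates 9 to 16. Controls lay in fixed wells on each plate. Non-targeting wells were A01 and D09, and all 24 untreated wells were on 1 plate.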

Results

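Splicing of a panel of alternative exons was measured in N2A neuroblastoma cells after single-gene knockdowns, 2832 libraries with 2 per gene, so as to ask which proteins alter inclusion of each exon. Many of the targeted genes code for RNA-binding proteins, chromatin factors and transcription factors. Controls were 64 libraries with a non-targeting siRNA (32 wells), 64 mock-transfected libraries (32 wells), 48 untreated libraries (24 wells) and 64 libraries of a double knockdown of Mbnl1 and Mbnl2 (32 wells), whose proteins, the muscleblind-like factors, bind RNA and regulate alternative exons. Median totals were 32853.5 reads per library for the gene knockdowns, 29539 for non-targeting, 34873 for mock, 25678.5 for untreated and 19568 for Mbnl1+2. Inclusion is given as percent spliced in (PSI), the percentage of an event's reads that include the exon, for 65 events.

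Knocking down a gene lowered the reads of its own amplicon in 18 of the 19 cases in which the panel holds the targeted gene, by edgeR's quasi-likelihood test adjusted over the 19 genes. The neuronal RNA-binding protein gene Nova1 had 0 reads in both of its libraries against a mean of 295.9 counts per 1000000 reads (CPM) ± 121.4 (SD, n = 64) in non-targeting libraries, at least 4.25-fold lower with the floor of 3 reads taken over both libraries (adjusted p = 2.84e-06). Elavl4, which codes for a neuronal ELAV protein, fell by 4.17 ± 0.35 (log2) and Celf6 fell by 3.96 ± 0.89. Clasp2, a microtubule plus-end protein, fell by 3.59 ± 0.16, and Srsf10, an SR-like splicing factor, fell by 3.44 ± 0.14. Med23, a Mediator subunit, fell by 2.87 ± 0.48, Ptbp2, the neuronal polypyrimidine tract-binding protein, fell by 2.75 ± 0.24, Kifap3, a kinesin-associated protein, fell by 2.36 ± 0.43 and Pbrm1, a subunit of a SWI/SNF complex, fell by 2.23 ± 0.24. Celf5 had 1 read over both libraries, a 7.50-fold lower level with a counting interval of 1.35 to 296.2, and 15 of the 64 non-targeting libraries also had 0 reads of it. The exception was Rbm26, whose amplicon changed by 0.04 ± 0.18 (p = 0.81) in the libraries labelled Rbm26 knockdown, where it stood at 9931 and 7495 CPM. Elavl3 had 3 reads, a 6.04-fold lower level (counting interval 2.07 to 29.3). The falls of Celf5 and Elavl3 did not pass without replicate 2, with adjusted p = 0.0695 and 0.127.

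Silencing Mbnl1 and Mbnl2 together lowered inclusion of 20 of the 65 events and raised 4 by at least 5 points. The strongest change was in Numa1, which codes for a spindle protein, where inclusion of a 42 nt exon (chromosome 7, 109150809 to 109150850) was 70.9% ± 4.94 (SD, n = 64) with the non-targeting siRNA and 11.4% ± 4.21 (SD, n = 64) with Mbnl1+2, a change of -59.6 ± 1.04 points. A 27 nt exon of the kinesin gene Kifc3 (chromosome 8, 97624547 to 97624573) went from 77.1% ± 9.002 (SD, n = 61) to 26.05% ± 9.88 (SD, n = 64), a change of -51.1 ± 1.55 points. Inclusion fell by 24.8 ± 0.358 points in the casein kinase gene Csnk1g3, by 20.5 ± 1.30 points in Syne2, a nuclear envelope protein gene, and by 15.99 ± 1.41 points in Dock7, a guanine nucleotide exchange factor gene. The other large falls were -12.7 ± 0.779 points in 2410002O22Rik, -11.9 ± 0.659 in Rbm26, -11.6 ± 2.62 in Ddhd1, -11.6 ± 0.822 in Clasp2 and -10.8 ± 1.66 in Med24. Inclusion rose in Atp9b (8.12 ± 1.89 points, n = 35 against 59), the kinase gene Mast2 (7.78 ± 0.687), Lsm14b (6.05 ± 1.40) and Ptbp2 (5.48 ± 0.773).

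The limma test called these 24 events and put 44 of the 65 past an adjusted p of 0.05. Of these 24 events, 22, 20, 22 and 21 were also called within the 4 sequencing batches taken singly, and all 24 had the same sign in each batch. Without replicate 1 the calls of Atp9b (5.12 points, adjusted p = 0.126), Ddhd1 (-7.40, 0.0615) and Lsm14b (5.49, 0.059) ended, and without replicate 2 those of Ap1g1 (-4.24 points) and Ptbp2 (4.51 points) fell short of 5 points. Mbnl1+2 libraries were shallower than non-targeting libraries, and with a minimum of 100 reads the count of calls was 14.

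**Figure D1:**
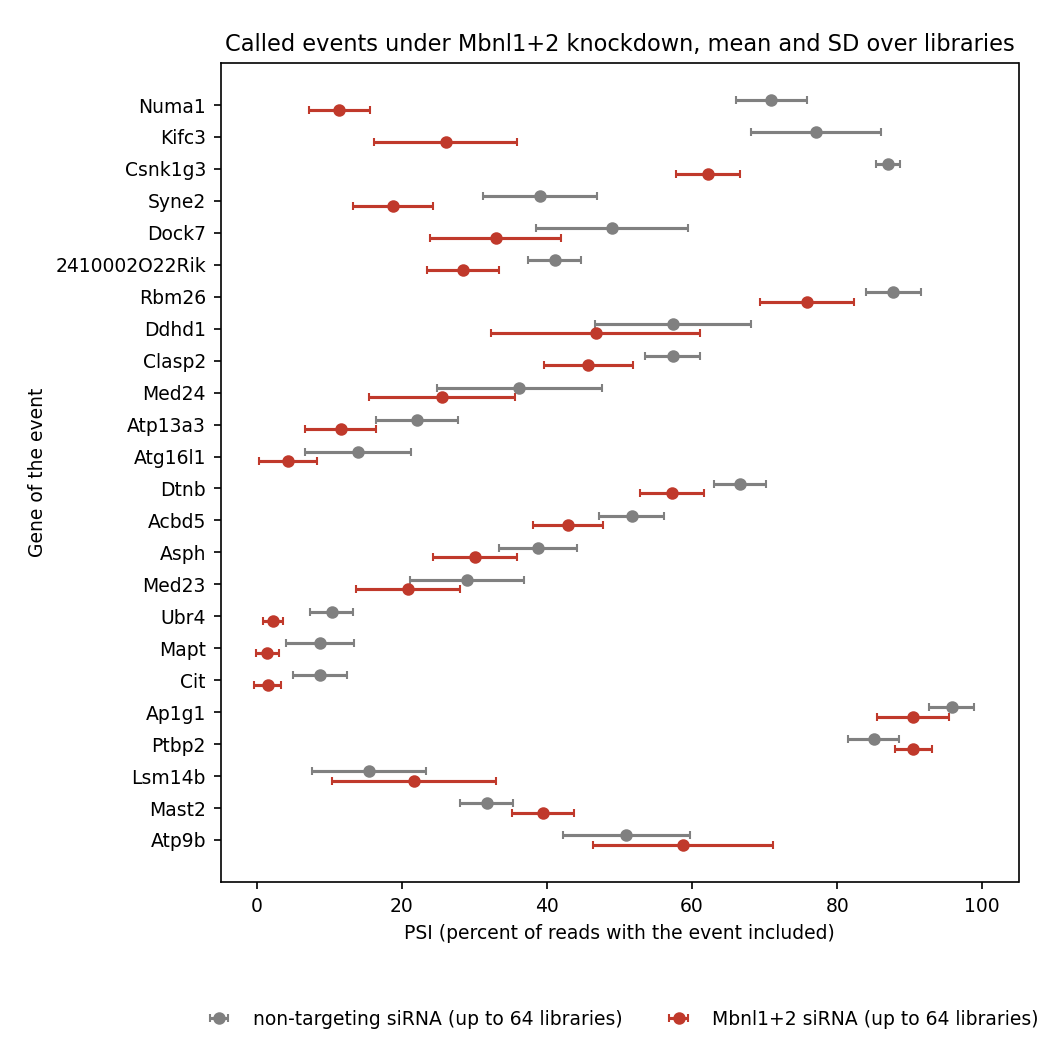
Mean PSI in percent (horizontal axis) of the 24 events called under Mbnl1+2 knockdown, one row per gene, for non-targeting libraries (grey) and Mbnl1+2 libraries (red), with up to 64 libraries per group and bars of 1 SD. Numa1 lies at 70.9% against 11.4% and Kifc3 at 77.1% against 26.05%, while the 4 events that rose differ by 8.12 points or less.

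Reads of whole amplicons also shifted under Mbnl1+2 knockdown, mostly by little, and the amplicons named here were chosen after their values were seen. The largest rise among the amplicons that passed was that of Nav3, by 1.54 ± 0.27 (log2) from a low mean of 35.5 CPM. The largest fall was that of Plekha6, which fell by 0.75 ± 0.31 and did not pass without replicate 1 (adjusted p = 0.113) or replicate 2 (0.0673). The amplicon of the microtubule-binding protein gene Mapt rose by 1.06 ± 0.05, that of Numa1 by 0.82 ± 0.06 and that of the autophagy gene Atg16l1 by 0.74 ± 0.05, while Sbno1 fell by 0.54 ± 0.05 and Evl fell by 0.54 ± 0.06 (n = 64 libraries per group). By edgeR's quasi-likelihood test 64 of 108 amplicons passed an adjusted p of 0.05, 25 higher and 39 lower, with a median absolute log2 change of 0.29. Only 2 of them changed by 1 or more on the log2 scale, and 57 had the same sign in all 4 batches. The same test put 7 amplicons past the threshold for mock and 0 for untreated libraries. For small changes under Mbnl1+2 the direction, and so the split into higher and lower, depended on the TMM normalization. Srsf10, for example, counted as lower by 0.11 (log2) although its mean was 91687 CPM under Mbnl1+2 against 90412 in non-targeting libraries.

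Mock and non-targeting libraries differed little in inclusion. Between mock and non-targeting libraries, 0 of 65 events were called by limma, 0 passed the adjusted threshold and 9 had an unadjusted p under 0.05, with a largest difference of 4.77 points. Untreated libraries had higher inclusion than non-targeting libraries in 3 events, namely 16.99 ± 4.70 points in the neuron navigator gene Nav1, 9.47 ± 3.05 points in the inositol trisphosphate receptor gene Itpr1 and 5.20 ± 1.57 points in Clasp2. All untreated wells lay on 1 plate, and the sizes depended on the plate term, without which Itpr1 differed by 1.74 points (adjusted p = 0.574) and Nav1 by 8.01 (0.0524). With a minimum of 5 reads the differences were 6.92 (0.286) and 8.50 points (0.326). Those 3 calls did not hold in every setting. With the non-targeting wells in position A01 alone there were 0 calls, and with those in D09 alone 5 for untreated and 4 for mock. Without replicate 1 there was 1 call (Clasp2), and without replicate 2 there was 1 call, in Asph, with 0 of the 3. The differences themselves kept their direction. With A01 alone they were 13.3 points in Nav1 (adjusted p = 0.276), 9.74 in Itpr1 (0.149) and 3.79 in Clasp2 (0.475). Without replicate 1 Nav1 differed by 17.6 (0.198) and Itpr1 by 7.27 (0.552). Without replicate 2 they differed by 14.5 (0.258) and 11.6 (0.167), and Clasp2 by 4.77 (0.0179). Within batches L2 and L4, 1 of the 3 events was called in each, and all 3 kept their sign in both.

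The knockdowns with most called events were mostly of core spliceosome components, and most of those events lost inclusion. Sf3a3, a subunit of the SF3A complex of the U2 small nuclear ribonucleoprotein (snRNP), lowered inclusion of 28 events, and the SF3 subunits Sf3b2, Sf3a1, Sf3b1 and Sf3a2 changed 27, 24, 24 and 24. The Sm protein Snrpe changed 26 events, Ik 23, and the SF3B subunit Sf3b4 and the 3' splice site factor U2af2 changed 21 each. Without replicate 2 the counts of Ik and U2af2 were 14 and 12. With a minimum of 100 reads, which left 35 events to test, Sf3a3 and Snrpe had 16 calls, Sf3b2 and Sf3a1 15, U2af2 11 and Sf3b1 9. Of the Sf3b1 libraries, 1 had under 10000 reads, and leaving it out gave 0 calls for Sf3b1, since a call needed both libraries. Several of these knockdowns changed most a 30 nt exon of Ppp3cb, a calcineurin catalytic subunit gene, whose inclusion was 97.6% ± 0.556 (SD, n = 64) in non-targeting libraries. It changed by -62.0 ± 0.783 points with Sf3a3, -54.5 ± 0.783 with Sf3a1, -55.1 ± 0.783 with Sf3b1, -43.4 ± 0.783 with Snrpe, -37.4 ± 0.783 with Ik and -32.7 ± 0.783 with Snrpd3. That error is pooled over all groups and understates the spread of some of these knockdowns. Their libraries stood at 42.51% and 28.97% with Sf3a3 and at 70.25% and 50.72% with Ik, but at 55.2% and 53.23% with Snrpe.

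Among the other leading knockdowns, Snrpd1 had 19 calls, Eftud2, Sf3b3 and Snrpd3 had 17, Prpf38a 16, Prpf8, Snrpg and Snrnp200 15, and Polr2d, Puf60, Snrpb, Srsf3 and Crnkl1 14. Without replicate 2 the counts were 10 for Eftud2, 8 for Prpf38a, 9 for Snrnp200, 9 for Snrpb and 7 for Srsf3. The largest changes were -48.2 ± 3.49 points in Herc4 for Sf3b2, -40.4 ± 4.53 in Numa1 for Sf3a2, -40.6 ± 3.46 in Sgce for Sf3b4, -53.0 ± 6.69 in Kifc3 for U2af2 and -44.6 ± 6.75 in Kifc3 for Sf3b3. Gatad2a changed by -41.2 ± 6.41 points with Snrpd1, Dock4 by -38.7 ± 7.59 with Eftud2 and -30.0 ± 7.59 with Snrpg, Clasp2 by -43.0 ± 3.58 with Prpf38a and -28.1 ± 3.58 with Crnkl1, and Ktn1 by -48.5 ± 8.49 with Prpf8. Ptbp2 changed by -32.8 ± 3.37 points with Snrnp200, -38.4 ± 3.37 with Puf60 and -31.8 ± 3.37 with Srsf3, and Ddhd1 by -43.4 ± 8.51 with the RNA polymerase II subunit Polr2d and -41.6 ± 8.36 with Snrpb. Of these, Dock4 with Eftud2 and Ddhd1 with Snrpb were not called without replicate 2 (-28.1 points each), nor was Dock4 with Snrpg without replicate 1 (-23.4). Reads were few in some, with lowest counts of 21 for Herc4 with Sf3b2, 20 for Dock4 with Eftud2, 24 for Ktn1 with Prpf8 and 26 for Ddhd1 with Snrpb. The libraries stood at 49.9% and 31.78% for that Herc4 change and at 31.59% and 10% for Dock4 with Eftud2. The main fit did not weight libraries by reads, so the printed errors do not reflect these low counts. Knockdowns in no list also ranked high. Tcf12, a basic helix-loop-helix transcription factor, raised 18 events and lowered 0, with 56.1 ± 3.44 points in 1700021K19Rik. Cpne1 (a copine) raised 15 and lowered 0, with 40.3 ± 3.44 points in the same exon. Leprel4 lowered 15, with -45.3 ± 7.68 points in Smc5 on 24 reads in each library, which was not called without replicate 1 (-42.7). With a minimum of 100 reads the counts were 9 for Leprel4 and Puf60, 8 for Sf3b3, 7 for Srsf3 and 6 for Tcf12 and Prpf38a. Srsf3, an SR protein, raised 8 events and lowered 6.

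Over all 89877 pairs of event and knockdown, 4388 passed an adjusted p of 0.05 and 2673 were called, 1909 of them lower. Lower calls thus made up 71.4%, and 58.7% when each library was centred on the median of the knockdowns on its plate. At least 1 event was called in 58.8% of the knockdowns, at least 3 in 22.03% and at least 10 in 3.11%. In control wells tested as if they were knockdowns, 2 events were called in 32 non-targeting wells, 1 in 32 mock wells and 3 in 24 untreated wells, or 19 in all with the replicate block. With a minimum change of 20 points the count of called pairs was 910.

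**Figure D2:**
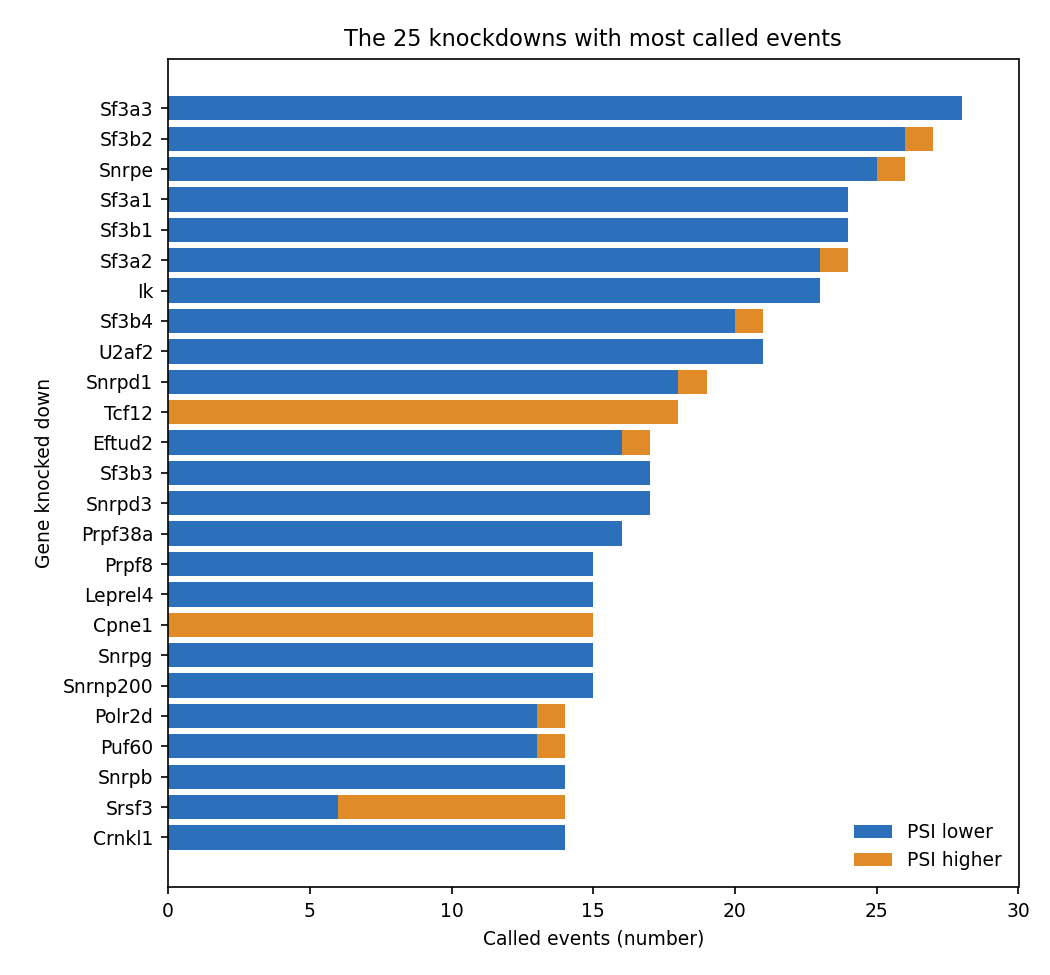
Number of called events (horizontal axis) for each of the 25 knockdowns with most calls, split into events with lower PSI (blue) and higher PSI (orange), from 2 libraries per knockdown. Sf3a3 lowered 28 events, whereas Tcf12 raised 18 and Cpne1 raised 15.

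Some exons responded to knockdown of many genes. Numa1 was called in 18.9% of knockdowns and lower in 18.6%, with -54.1 ± 4.53 points for Arrdc4 at most. Clasp2 was called in 18.1% (15.6% lower, -48.5 ± 3.58 points with Sf3a3), Mast2 in 14.3% (7.13% lower and 7.20% higher, 38.5 ± 3.00 points with Tcf12), Tnik in 10.03% (35.03 ± 3.56 points with Cpne1) and Acbd5 in 9.11% (-43.8 ± 3.60 points with Sf3a3). Ptbp2 followed with 8.76%, with -58.2 ± 3.37 points after knockdown of Eif4a3, the helicase of the exon junction complex. Sgce was called in 7.98% (-50.1 ± 3.46 points with Sf3a1), 2410002O22Rik in 7.84% (-31.2 ± 3.40 with Hnrnpu), Dtnb in 7.06% (-41.2 ± 2.44 with Rbfox2) and Kifc3 in 6.51% (-57.3 ± 6.69 with Son). A single event in each of Celf4, Celf6, Dlg1, Kifap3, Nktr, Phf21a, Sbno1, Snap91 and Srsf10 was called in 0 knockdowns by limma. Those in Phf21a and Sbno1 had some calls without replicate 1. The other Celf6 event was called in 5 knockdowns. Apart from Dlg1 (24.9%), the uncalled events lay near an end of the PSI scale in non-targeting libraries, such as 100% in Celf4 and 1.60% in Nktr. They thus had little room to change in 1 direction. The order of the most often called exons was not stable. Without replicate 1 Clasp2 was called in 26.8%, Numa1 in 20.7%, Ptbp2 in 14.8%, Sgce in 13.6% and Tnik in 5.51% of knockdowns. Without replicate 2 the share was 6.02% for Tnik, 5.53% for Acbd5 and 2.44% for Kifc3. Kifc3 reached 11.1% with mock wells as controls, and at a minimum of 20 points Numa1 was called in 8.40% and Clasp2 in 5.37%.

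Of 26 gene lists, 6 had more called events per knockdown than the other knockdowns, and all 6 hold parts of the splicing machinery. The Sm core (6 genes) averaged 15.3 ± 8.21 (SD) called events and the U2 snRNP with SF3 and 3' splice site factors (22 genes) 12.2 ± 9.48, each with adjusted p = 0.00013 from the smallest p that the permutations can give (1e-05). The exon junction complex and its periphery (8 genes) averaged 5.88 ± 4.09 (permutation test, adjusted p = 0.0293), Prp19 complex and catalytic-step factors (36 genes) 4.44 ± 5.38 (0.00113), the U4/U6.U5 tri-snRNP with LSm proteins (22 genes) 4.23 ± 5.54 (0.0191) and SR and SR-related proteins (28 genes) 4 ± 3.93 (0.0168). All other knockdowns averaged between 1.72 and 1.87 in these comparisons. Leading members were Snrpe, Snrpd1, Snrpd3 and Snrpg of the Sm core, Sf3a3, Sf3b2, Sf3a1 and Sf3b1 of the U2 list, and Eftud2, Prpf8, Snrnp200 and Naa38 (10 calls, -31.1 ± 3.58 points in Clasp2) of the tri-snRNP list. Ik, Prpf38a, Crnkl1 and Smu1 (13 calls, -22.4 ± 6.16 points in Dock7) led the Prp19 list, which spans several stages of the spliceosome and is not a single complex. In the exon junction complex list, Rnps1 had 13 calls, Magoh 9 with -54.4 ± 3.37 points in Ptbp2, Pnn 8 with -42.9 ± 3.58 points in Clasp2, and Rbm8a 7 with -56.1 ± 3.37 points in Ptbp2. SR list leaders were Srsf3, Srrm4, Bclaf1 (12 calls, -32.0 ± 2.44 points in Dtnb) and Srsf2 (9 calls, all higher, 44.9 ± 3.44 points in 1700021K19Rik). The tri-snRNP list did not pass without replicate 1 or replicate 2 (adjusted p = 0.0663 and 0.0788), nor the exon junction complex (0.0953) and SR lists (0.0549) without replicate 2, and with a minimum change of 20 points 2 lists passed, the Sm core and the U2 list.

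The other 20 lists did not pass. RNA polymerase II and elongation factors (21 genes) averaged 3.62 called events (adjusted p = 0.0725, and 0.0331 with the replicate block), led by Polr2d. hnRNP proteins (30 genes) averaged 3.17 (0.0831, Hnrnph1 13 calls), U1 snRNP factors (9 genes) 3.22 (permutation p = 0.153, adjusted 0.306, Snrnp70 10) and tissue-regulated splicing factors (30 genes) 2.83 (0.214, Srrm4 12). Means were 2.75 for SR protein kinases (adjusted p = 0.574, Srpk1 12), 2.13 for histone deacetylases and sirtuins (0.848, Sirt1 14), 2.00 for the minor spliceosome (0.956, Snrnp25 9), 1.75 for other RNA recognition motif proteins (0.848, Sfpq 9) and 1.64 for mRNA export (0.848, Ncbp2 5). They were 1.44 for SWI/SNF (0.701, Arid1a 7), 1.37 for kinetochore and centromere proteins (0.512, Cenpe 7), 1.29 for 3' end processing (0.622, Cpsf4 4) and 1.24 for zinc finger transcription factors (0.143, Zfp295 9). Below the mean of 1.89 over all knockdowns also lay nucleoporins at 0.917 (0.396, Nup98 4), Polycomb at 0.867 (0.320, Pcgf2 4), the small RNA pathway at 0.818 (0.376, Prkra 4), RAS and MAP kinase signalling at 0.786 (0.307, Araf 2), SMN and snRNP assembly at 0.538 (0.214, Smn1 3), arginine methyltransferases at 0.5 (0.307, Prmt8 2) and DNA replication at 0.400 (0.0741, Orc3 2).

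**Figure D3:**
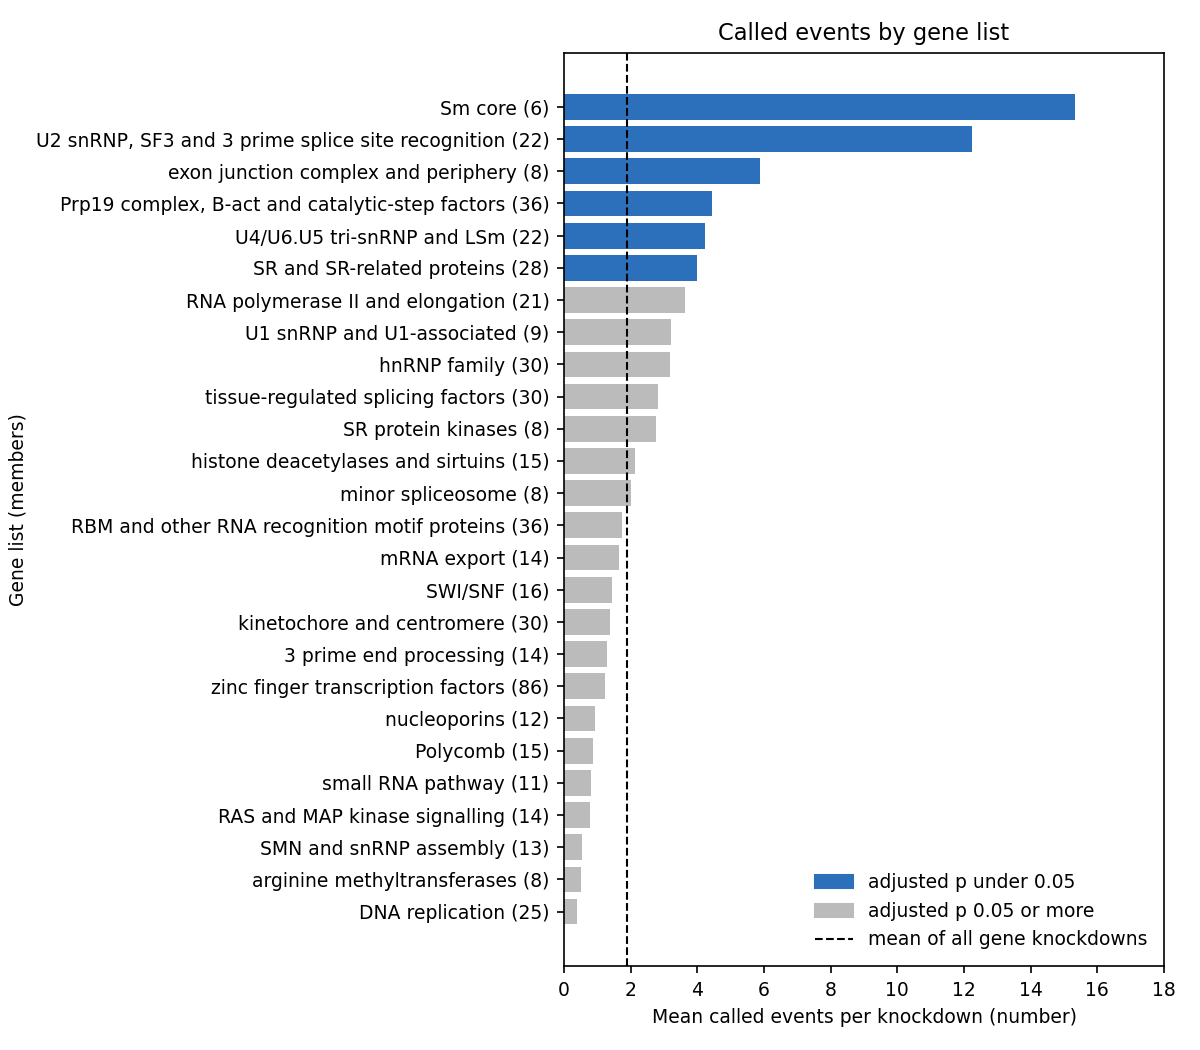
Mean number of called events per knockdown (horizontal axis) in each of 26 gene lists, with the number of members in parentheses. Blue bars have an adjusted p under 0.05 and the dashed line is the mean of all gene knockdowns, 1.89. The Sm core at 15.3 and the U2 snRNP list at 12.2 stand highest, and DNA replication at 0.400 is lowest.

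Among 30 splicing regulators of a list fixed in advance, 29 changed at least 1 event, and their mean of 6.87 called events became 7.73 when adjusted over the list alone. Srrm4, the neural activator of microexons, lowered 11 events and raised 1, with -46.9 ± 3.58 points in Clasp2, -37.5 ± 7.70 in Dock4 and -36.8 ± 1.65 in Kif1b. Rnps1 lowered 12 and raised 1, with -27.1 ± 1.06 points in the transcription factor gene Mef2d, 25.3 ± 3.20 in Sbf2 and -24.5 ± 3.58 in Clasp2, and Srsf11 lowered 5, with -19.8 ± 3.58 in Clasp2, -18.0 ± 5.20 in Lsm14b and -15.4 ± 3.37 in Ptbp2. Ptbp1, a repressor of neural exons, went the other way, since 10 events rose and 0 fell. Its largest changes were 34.6 ± 3.44 points in 1700021K19Rik, 31.9 ± 5.20 in Lsm14b (22 and 24 reads) and 26.9 ± 3.20 in Sbf2. Its neuronal paralog Ptbp2 had 3 calls, 5 with the replicate block, with -37.8 ± 3.37 points in the exon of its own transcript, -13.1 ± 3.60 in Acbd5 and 12 ± 3.44 in 1700021K19Rik. Without replicate 2 Rnps1 had 6 calls and Srsf11 2, and Ptbp1 had 6 without replicate 1 and 5 with a minimum of 100 reads. Calls lost with a replicate left out were Dock4 under Srrm4 (-30.3 points, adjusted p = 0.108), Lsm14b under Srsf11 (-17.98 without replicate 1, -17.8 without replicate 2) and, for Ptbp2, Acbd5 (-11.4, 0.114) and 1700021K19Rik (8.69, 0.293).

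Among tissue-regulated factors, Rbfox2 lowered 6 events (-41.2 ± 2.44 points in Dtnb, -35.3 ± 4.53 in Numa1, -28.2 ± 5.53 in Syne2) and Rbfox1 lowered 2 (-17.5 ± 4.53 in Numa1, -14.9 ± 2.44 in Dtnb). Mbnl1 alone changed 6 events, with -52.9 ± 4.53 points in Numa1, -40.6 ± 6.69 in Kifc3 and -17.5 ± 1.56 in Csnk1g3. Mbnl3 lowered 2, with -35.9 ± 4.53 in Numa1 and -21.0 ± 6.69 in Kifc3, and Mbnl2 lowered 2 others, with -22.2 ± 3.58 in Clasp2 and -13.1 ± 4.01 in Asph. Elavl1, an RNA-stability factor, changed 6 events, with 27.5 ± 3.40 points in 2410002O22Rik, -17.4 ± 0.34 in Elavl4 and -13.5 ± 2.41 in Mapk8. Celf1 lowered 3 (-23.8 ± 1.06 in Mef2d, -17.4 ± 2.87 in Rbm26, -14.6 ± 4.53 in Numa1), Khdrbs1 changed 1 (31.9 ± 3.46 in Sgce), and Qk changed 5 (22.5 ± 6.93 in Med24, -19.0 ± 3.40 in 2410002O22Rik, 17.4 ± 3.00 in Mast2). Rbm38 changed 4 (22.8 ± 5.53 in Syne2, 20.7 ± 3.44 in 1700021K19Rik, 14.7 ± 3.56 in Tnik), and Nova1, whose own amplicon was at 0 reads, changed 0 events by limma. Several of these calls depended on the setting. Without replicate 1 or with 5 reads Celf1 had 5 calls, and 6 without the plate term. Qk had 3 with either replicate left out, and Rbm38 had 9 with plate median centring, 2 when weighted by reads and 0 with a minimum of 100 reads. Without replicate 2, Numa1 under Rbfox1 changed by -10.5 points (adjusted p = 0.276), Kifc3 under Mbnl3 by -11.5 (0.738), Numa1 under Celf1 by -11.0 (0.238), and Syne2 and Tnik under Rbm38 by 19.1 (0.0603) and 10.3 (0.244). The call of Kifc3 under Mbnl3 also ended with 5 reads (-20.8 points, 0.0546), the logit scale (-21.0, 0.118) and D09 wells only (-20.3, 0.0636), at a similar change, and with plate median centring (-14.9, 0.121). Asph under Mbnl2 was not called without replicate 1 (-15.4 points, 0.0772) or replicate 2 (-10.8, 0.326). Med24 under Qk kept its size but not its call without replicate 1 (23.05 points, 0.313), without replicate 2 (22.6, 0.345) and with 5 reads (21.95, 0.053), and was smaller without the plate term (14.02, 0.223), with plate median centring (16.4, 0.0607) and with A01 wells only (15.3, 0.275).

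Of the hnRNP proteins in that set, Hnrnpl changed 6 events (-37.9 ± 4.53 points in Numa1, -19.5 ± 3.37 in Ptbp2, -14.5 ± 1.56 in Csnk1g3) and Hnrnpk 6 (-32.7 ± 6.43 in Gatad2a, 28.9 ± 5.56 in Syne2, 28.7 ± 6.90 in Med24). Hnrnpc had 2 calls, -13.2 ± 3.58 in Clasp2 and 18.5 ± 5.89 in Med23, and the latter rested on 1 library, with a change of 0.622 points without replicate 2. The SR protein Srsf1 lowered 8 events and raised 1 (-40.7 ± 3.58 in Clasp2, -25.1 ± 3.60 in Acbd5, -24.6 ± 4.01 in Asph), Srsf3 also gave 28.4 ± 2.54 in Mgrn1 and -27.6 ± 8.36 in Ddhd1, and Tra2b raised 3 (15.3 ± 4.01 in Asph, 11.2 ± 3.58 in Clasp2, 10.6 ± 3.00 in Mast2), of which 0 were called without replicate 2. The 3' splice site factors gave -43.9 ± 6.41 points in Gatad2a and -30.9 ± 3.60 in Acbd5 for U2af2, -48.1 ± 3.37 in Ptbp2 and -47.9 ± 1.56 in Csnk1g3 for Sf3b1, and -37.6 ± 8.66 in Nav1 and -34.0 ± 8.67 in Ktn1 for Puf60. Prpf8 gave -41.1 ± 3.58 in Clasp2 and -35.2 ± 7.06 in Smc5. With replicate 1 or replicate 2 left out, 4 of these events changed by about as much but were not called, namely Med24 under Hnrnpk (24.9 and 32.7 points), Ddhd1 under Srsf3 (-23.4 and -30.4), Nav1 under Puf60 (-38.002 and -37.7) and Smc5 under Prpf8 (-37.02 and -32.8). Nor was Gatad2a under Hnrnpk called without replicate 2 (-25.5 points, adjusted p = 0.205) or Ktn1 under Puf60 without replicate 1 (-29.6, 0.348).

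Tardbp changed 4 events (17.3 ± 3.86 points in Atp13a3, -16.7 ± 4.53 in Numa1, -14.5 ± 2.44 in Dtnb) and Fus 1 (-25.2 ± 6.81 in Atp9b), both RNA-binding proteins known from motor neuron disease. The transcription factor Nacc1 changed 5 (-42.9 ± 4.53 in Numa1, 28.04 ± 6.85 in Med24, -23.9 ± 5.53 in Syne2) and Rest, the repressor of neuronal genes, 2 (-16.8 ± 4.53 in Numa1, 10.3 ± 3.00 in Mast2). The Fus event was not called without replicate 1 (-29.9 points, adjusted p = 0.0649) or replicate 2 (-20.6, 0.437), and neither were the Rest events without replicate 2 (-14.3 in Numa1 and 10.01 in Mast2). Numa1 under Tardbp (-15.1 points, adjusted p = 0.0541) and Med24 under Nacc1 (21.1, 0.382) were not called without replicate 1, nor was Atp13a3 under Tardbp (12.6, 0.124) without replicate 2.

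Microexons, which are very short exons enriched in neurons, lost more inclusion than longer cassette exons after knockdown of Srrm4 and of Rnps1. The classes started from unlike inclusion, however. No microexon was under 24.1% (Trappc9) in non-targeting libraries, whereas longer exons such as Nktr at 1.60%, Pbrm1 at 2.21% and Kifap3 at 2.66% could lose little. The permutation did not adjust for this, so exon length was not separated from starting inclusion. With Srrm4 the mean change was -11.6 ± 16.3 points (SD, 19 microexons) against -3.49 ± 10.3 (SD, 37 longer exons), a difference of -8.09 points (permutation p = 0.025, adjusted p = 0.0375). With Rnps1 it was -11.5 ± 9.82 (19) against -1.48 ± 8.45 (32), a difference of -10.0 points (adjusted p = 0.00135). With Srsf11 it was -4.63 ± 7.08 (19) against -3.48 ± 6.93 (36), a difference of -1.14 points that did not pass (adjusted p = 0.565). Limiting microexons to 15 nt left 2 of them and turned the differences to 2.03 points for Srrm4 and 4.95 for Rnps1 (adjusted p = 1 for both), and without replicate 1 the Srrm4 difference was -8.16 points (adjusted p = 0.0524).

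Knockdowns of proteins of the same list changed the exons of the panel more alike than random sets of knockdowns did in 5 of 6 lists of spliceosome parts. Random sets were drawn from knockdowns with at least 1 call and were not matched for the number of calls. The test thus cannot separate membership of a list from a likeness of knockdowns with many calls, and likeness between lists was not tested. The mean correlation of PSI change profiles between members with a call was 0.548 in the Sm core (6 members), 0.376 in the tri-snRNP (15), 0.323 in the U2 list (20), 0.312 in the exon junction complex (8) and 0.199 in the Prp19 list (26). Random sets of the same size averaged 0.0736 to 0.0752, and permutation p over random sets, adjusted over 6 lists, was 0.0002 for the 3 highest, 0.00072 for the exon junction complex and 0.00045 for the Prp19 list. The U1 list (6 members) had 0.0872 and did not pass (permutation adjusted p = 0.39). Since all profiles share the non-targeting wells, simulated unchanged knockdowns correlate at 0.0295 with a covariance of 0.454. Mean covariances were 56.7 in the Sm core, 46.6 in the U2 list, 25.5 in the exon junction complex, 20.7 in the tri-snRNP, 11.6 in the Prp19 list and 5.49 in the U1 list, and splitting the controls between members left the correlations at 0.543 for the Sm core and 0.319 for the U2 list.

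The authors' deposited table of normalized PSI changes ran close to the changes computed here, with Pearson r = 0.951 and Spearman rho = 0.916 over 84307 pairs, which are not independent replicates. In the authors' deposited values, 2510 pairs reached both a change of 10 points and an absolute SSMD of 2, and 2097 of them were also called here, all with the same sign. For Mbnl1+2 the authors' deposited expression table holds 58 amplicons with an FDR under 0.05, and its log2 changes correlated with those computed here at r = 0.947 across amplicons.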

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

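Tests of depth and of profile similarity for Tcf12, Cpne1 and Leprel4, of the noise of the Numa1 event, of depth behind the Mbnl1+2 amplicons and of splits within the plate of the untreated wells were chosen after the result was seen, and the third pattern below was picked after its counts were known.

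Elements outside the 65 main events were in no comparison above, and their calls mostly repeated those of main events. Among 38 such elements, 90 pairs with a knockdown were called, against 0 in 88 control wells tested in the same way, and 5 knockdowns had a call in such elements alone. An alternative element of Mapk8, the gene of the kinase JNK1, was called in 66 knockdowns, 37 higher and 29 lower, with -29.1 ± 2.47 points at most for Polr2d. Its mean PSI in non-targeting libraries was 47.7% ± 3.15 (SD, n = 64), against 52.5% ± 2.99 for the main Mapk8 exon. The changes of both elements correlated at r = -0.994 across knockdowns, 61 of 61 shared calls being in opposite directions. The 2 values are close to complementary, so these opposite moves repeat the main exon and are not separate results. A second element of Gatad2a, a subunit gene of the NuRD complex, was called in 16 knockdowns, 4 higher and 12 lower, with -37.8 ± 7.05 points at most for Sf3a3. All 16 moved with the main Gatad2a exon, which the deposited design joins to that element, so they are not separate results either.

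Knockdown of Tcf12 and Cpne1 raised 18 and 15 events and lowered 0, and Leprel4 lowered 15, although none of them belongs to a splicing list. Low depth is argued against for Tcf12 and Leprel4, since knockdowns at most as deep had a median of 1.5 and 2 called events. The libraries of Cpne1 were deeper than those of most knockdowns. Low depth was thus no candidate there, and the median of 1 does not test it. Carry-over between wells is argued against. Only 10.42% of the 48 called events (5) had an adjacent well with a called change of the same sign and at least equal size. A candidate explanation is that the siRNA pools for Tcf12, Cpne1 and Leprel4 also silence a splicing factor. The Leprel4 profile was closest to that of Snrpg (r = 0.851 across events), which this explanation allows. Aqr and Prpf8 came next, so the match does not single out a silenced factor. It was the best match among all listed splicing factors, with no baseline from knockdowns with many calls. Tcf12 and Cpne1 were closest to each other (0.882) and next to Mysm1 (0.878 and 0.842). They matched their nearest listed factor, Ptbp1, at 0.7979 and 0.7052. The explanation thus stays open for Tcf12, Cpne1 and Leprel4. A profile match cannot separate an off-target effect from regulation of that factor by the targeted gene, which was not tested, and unchanged knockdowns correlate at 0.0295 through shared controls.

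Numa1 inclusion fell in 18.6% of knockdowns, and 57.6% of these are in no list, against 62.4% of all knockdowns. Carry-over from the Mbnl1+2 wells, where the exon is nearly lost, is argued against, since 15.53% of these knockdowns lay beside such a well, against 15.6% of all knockdowns. Noise of the event is argued against by the control wells, of which 0% (0 of 64, which allows up to 4.69%) had a called fall in contrast to the knockdowns. The position of the non-targeting wells is argued against as the whole cause, since centring on the plate median kept 77.65% of the falls, but it may contribute to the rest. That the exon responds to many perturbations of the cell stays open as a hypothesis.

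Under Mbnl1+2 knockdown, 12 of the 20 genes with an event that lost inclusion had more amplicon reads and 4 had fewer by the edgeR test. Those 4 falls (Clasp2, Dtnb, Med23 and Rbm26) were small, at log2 changes of -0.08 to -0.13, and their direction depended on the normalization. Mean CPM was slightly higher under Mbnl1+2 in all 4, at 24107 against 23233 in Clasp2 for example. If shorter products amplify or sequence better, inclusion and reads should oppose each other across knockdowns, and they did in 75.61% of 41 events, which lies between the bounds set in advance for and against it. Longer exons had steeper slopes (Spearman rho -0.4863 across 41 events, permutation p = 0.00144), as an effect of product length predicts. The lower depth of the Mbnl1+2 libraries predicted a median of 19.1% of the rises, with a bootstrap interval of 3.83 to 45.8 that is too wide to exclude it. Product length may thus account for part of the change, and a change in transcript abundance stays open.

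Chance could be set against the group comparisons with 100 splits of the wells, the real split included, drawn so that both libraries of a well stayed together. For Mbnl1+2, 1 split (the real one) gave as many as 24 called events, the highest other giving 5, so a chance division of the wells is excluded there. The same held for amplicon counts, where 1 split reached the real 64 and the highest other had 23. For untreated wells 1 split reached 3 and the highest other had 1, but those splits ran across plates. Within the plate of the untreated wells, which holds 2 non-targeting wells, 1 of 100 splits reached 3 and the highest other had 2. The real split was thus the highest of those drawn on that plate. Chance is not excluded there, since the comparison rests on 2 non-targeting wells and the 3 calls did not hold in every setting. An effect of well position was not tested, because those 2 wells have fixed positions. For mock, all 100 splits gave at least the real count of 0, and the highest other had 1.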

How the results depend on the processing

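Alternatives that used 1 position of the non-targeting wells or left out shallow knockdown libraries were chosen after the data were seen. Of 3342 recomputed values, 3031 were kept, which means the same direction and side of the threshold or, for counts and shares, a value within a fold limit set. Counts and shares beyond that limit made up 4.88%, while 4.19% of the values no longer passed, 6 newly passed and 2 reversed. A 5 point minimum and dropping the same-side rule only relax the calls, so these alternatives could not end a call of the screen. Called pairs of the screen stayed between 1886 and 3633 except with a minimum change of 20 points, which gave 910, with a call in 27.97% of knockdowns in place of 58.8%. Of the 98 named pairs, 36 had no value with 100 reads, and 32 of the other 62 were called in all 16 alternatives of the screen, while 15 were lost without replicate 1, 24 without replicate 2 and 28 at 20 points.

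Control wells had 6 calls, which became 24 with 5 reads, 1 with 100 reads, 19 with the replicate block, 11 in each run without replicate 1 or 2 (range 11 to 11), 27 with plate median centring, 14 with a 5 point minimum and 11 with D09 wells only. Mock had 1 call with 5 reads and 4 with D09 only. Untreated had 1 with 5 reads, 1 with 100 reads, 1 to 1 over the runs without a replicate (without replicate 2 in Asph, which is none of the 3), 0 with A01 only and 5 with D09 only. With 100 reads, which left 35 events to test in place of 65, 28 events had a call in place of 56 and Mbnl1+2 had 14 calls in place of 24.

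Lists past the threshold were 2 at 20 points and 3 to 5 without a replicate, in place of 6. At 20 points the excess of called events over other knockdowns was 1.29 for the tri-snRNP, 0.937 for the Prp19 list, 1.37 for the exon junction complex and 1.06 for SR proteins, and none of them passed. Without replicate 1 and without replicate 2 it was 1.64 and 1.37 for the tri-snRNP, 4.08 and 2.18 for the exon junction complex, and 1.83 and 1.41 for SR proteins, and only the exon junction complex and SR lists without replicate 1 still passed. RNA polymerase II and elongation factors passed with a 5 point minimum (2.23) and with the replicate block (2.23), and DNA replication with a 5 point minimum (-2.04). By the share of knockdowns with at least 3 calls, hnRNP proteins (31.98 points above other knockdowns), RNA polymerase II (25.97) and DNA replication (-22.4) passed, and the tri-snRNP (19.2) did not.

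Microexon differences reversed with a 15 nt limit, to 2.03 points for Srrm4 and 4.95 for Rnps1, where 2 microexons remained, and for Srrm4 ranged from -8.16 (adjusted p = 0.0524) to -7.94 without a replicate. In the runs without a replicate each knockdown has 1 library, assumed to vary like the other groups. The replicate block, with 3369 called pairs, changed the control wells (19), the Ptbp2 knockdown (5 calls) and the RNA polymerase II list (adjusted p = 0.0331) beyond the limits set and no other named result. Depth limits events with few reads, which left 65 main events to test. Otherwise the cause was not tested.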

Other observations

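Several knockdowns outside every gene list had called events mostly or only in a single direction, as values chosen after they were seen. Mysm1, a histone H2A deubiquitinase, raised 10 events and lowered 0, with 29.8 ± 3.44 points in 1700021K19Rik, 29.4 ± 3.56 in Tnik and 23.3 ± 3.20 in Sbf2. Adad1 raised 9, Rcc2 raised 8 and the transcription factor Tcf3 raised 7, each with 0 lowered. In the other direction the septin Sept2 lowered 13 events, Phf14 lowered 10, the transcription factor Cebpb lowered 9 and the cohesin loader Mau2 lowered 8, each with 0 raised. Dbr1, the lariat debranching enzyme, lowered 6 and raised 1.

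The deacetylase Sirt1 changed 14 events, 13 of them lower, with -27.3 ± 3.58 points in Clasp2, -23.9 ± 1.06 in Mef2d and -17.0 ± 1.65 in Kif1b, exons that also lost inclusion with Srrm4 or Rnps1. No test of a shared effect was run.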
